A study of Rattus norvegicus with 12 samples.

How the data were processed

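RNA was measured in 12 rat libraries. Per the labels, they were made from polyadenylated RNA of RIN above 7 with a KAPA stranded kit and 10 PCR cycles, and read on a NextSeq500 for 75 cycles. The groups were 4 libraries of primary Müller cell cultures, 5 of the SIRMu-1 line and 3 of the rMC-1 line. Samples were grouped by their labels alone. The labels call the samples of a group biological replicates and do not say which cultures shared an animal, so the p-values measure the spread between these libraries, which may in part be technical. All SIRMu-1 libraries are cultures of 1 line, and so are all rMC-1 libraries. Their spread is that between cultures of a line, so the p-values do not extend to other lines. The names of the authors' files carry a code that primary replicates 1 and 2 share, as do rMC-1 replicates 1 and 2, SIRMu-1 replicates 1 to 3, and SIRMu-1 replicates 4 and 5. Its meaning is not given in the sources used here. Libraries with the same code may stem from 1 animal or culture, in which case the p-values are too small. The counts did not settle this. Chi-square per gene between libraries of the same code was 148.8 in primary cultures (other pairs 221.3 to 338.6), 77.3 in rMC-1 (others 24.2 and 55.9) and 43.5 to 204.8 in SIRMu-1 (others 44.1 to 443.6).

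Per the submitters' processing notes, cutadapt 1.8.1, STAR 2.5.3a and edgeR 3.18.1 were used with genome build rn6. The role of each tool, the gene annotation and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table per library with whole-number read counts for 17315 genes, not normalized. The authors also deposited a log2 CPM table of 10236 genes for the same 12 libraries. Its values were matched, with a largest difference of 5e-14, by edgeR's log2 CPM with TMM factors and a prior count of 0.25 computed from the deposited counts of those genes. Each of its genes had over 1 CPM in at least 3 libraries, which 10576 genes of the count files had.

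The count files also held reads that belong to no gene, which were left out of library sizes and tests. Reads outside annotated genes were 24.2% to 30.3% of a library, reads mapping to several places 9.47% to 12.3%, unmapped reads 1.84% to 2.54% and ambiguous reads 0.15% to 0.19%. Reads in genes were 55.8% to 63.0%. Because reads with several mapping places were set aside, genes with near-identical copies, such as those of ribosomal proteins with their pseudogenes, have uncertain counts. Genes that overlap on opposite strands are uncertain too. Of the gene symbols, 14810 matched a symbol of the RefSeq rat annotation on assembly GRCr8 and 2114 matched a synonym only. That annotation was used for names alone, since the build differs.

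The counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter on the 3 groups, which left 11321 genes tested and 5994 not tested, and libraries were scaled by TMM factors. A quasi-likelihood model with 3 group means over all 12 libraries (9 residual degrees of freedom) gave the 3 comparisons between groups. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. "EdgeR adjusted p" below means this value. Log2 fold changes are given ± standard error, and levels as CPM (counts scaled to a common library size) on the TMM scale, mean ± SD. For the drugs, the SIRMu-1 cultures were split by gentamicin and amphotericin B into 2 libraries with and 3 without (8 residual degrees of freedom). Passage number was fitted as a number within SIRMu-1 with a drug term, over 10755 genes (2 residual degrees of freedom).

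The 28 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists with at least 3 tested genes. Camera was repeated with a correlation estimated from the data. Fry was run beside it, and tests only whether the genes of a list move, on balance, one way, without comparing them with other genes. The lists were markers of Müller glia, astrocytes, photoreceptors, inner retinal neurons, retinal pigment epithelium, microglia and macrophages, endothelium, and pericytes with smooth muscle; retinal progenitor genes, fibroblast and matrix genes, mitotic and replication genes, E2F targets of the G1/S step, p53 targets, and regulators of senescence and immortalization; genes of glutamate and glutathione handling, potassium and water channel complexes, retinoid handling, glycolysis, cholesterol synthesis, lysosomes and cytosolic ribosomal proteins; HIF targets, growth and neurotrophic factors, inflammatory, interferon-stimulated, Hox, stress and immediate early, and Y-linked genes. Some genes stand in several lists. The Müller glia and progenitor lists share Sox2, Notch1, Lhx2, Hes1, Nes and Pax6 among others, Glul and Slc1a3 are also glutamate genes, Rlbp1 is also a retinoid gene, and Cdkn1a is both a p53 target and a senescence regulator.

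The groups, tests, gene lists and most alternatives were fixed before the data were examined. So was the rule for named genes: 18 fixed genes in each comparison, of which Xist is not in the files; the 5 largest rises and falls among called genes with a mean log2 CPM of at least 3 and no overlap between the groups; and up to 2 members of each list in each direction with the largest called change. The text gives some of these list members, mostly those whose value did not rest on 1 library, and some of the named genes are not reported. A fold against a group with no counts is a lower bound, computed from 3 counts over the group. With 1 to 3 counts the ratio is given with its exact 95% counting interval. Reads carry no molecular identifiers, so such intervals and bounds cover counting error only.

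Alternatives were other scalings (RLE size factors, library totals), other filters on low counts, DESeq2 1.42.0, limma on the authors' log2 CPM table, the replicate number as a block, the 2 groups alone, glmTreat against a 1.5-fold change, subsets of the SIRMu-1 cultures, and leaving out each library in turn. Leaving out libraries in the passage fit and in the list tests was chosen after seeing the data, and so were summing the libraries that share a file-name code (3 primary, 2 SIRMu-1 and 2 rMC-1 samples, 4 residual degrees of freedom) and the code as a term in the drug and passage fits. Tables and plots were made with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

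No pair of libraries within a group held near-identical counts: the chi-square per gene was 24.2 to 444 over the 19 pairs within groups. The test was checked on counts simulated for the real genes with known changes. Each simulation changed only 67, 67 and 66 genes by 1.5-fold, 2-fold and 4-fold, while 46.1% to 70.8% of genes were called between the groups in the data. It therefore did not check the scaling under such wide change, and the shares called may differ in the data. It called 7.5%, 55.2% and 84.8% of genes changed 1.5-fold, 2-fold and 4-fold between SIRMu-1 and primary cultures over 11320 genes, with 7 false calls of 105. For rMC-1 against primary cultures these shares were 6%, 44.8% and 83.3% over 11317 genes, with 3 false calls of 92. For SIRMu-1 against rMC-1 they were 13.4%, 52.2% and 86.4% over 11320 genes, with 9 false calls of 110, and for the drugs 1.5%, 16.4% and 68.2% over 11321 genes, with 5 false calls of 62. Camera called a simulated list of 20 genes raised 2-fold and none of 20 random lists. Simulated genes were drawn independently, while genes of the real lists had estimated correlations of up to 0.85 (mitotic and replication genes). The list check therefore cannot show whether camera's preset correlation suits lists of correlated genes, and no conclusion on their camera p-values is drawn from it.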

Results

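Gene expression was measured by RNA sequencing in 3 kinds of cultured rat cells described as Müller cells, the main glial cells of the retina. The primary cultures (4 libraries, passage 3 or 4) came from pups. SIRMu-1 (5 libraries, passages 6 to 20) is a line of such cells that became immortal without an introduced gene. The rMC-1 line (3 libraries, passages 23 to 26) came from adult rats and was immortalized with the SV40 large T antigen. The medium held 25 mM glucose, with 20% serum for the primary and SIRMu-1 cultures and 10% for rMC-1. Gentamicin (87 mg/L) and amphotericin B (2.2 mg/L) were present in all primary cultures, in replicates 3 and 5 of SIRMu-1 and in no rMC-1 culture. Reads assigned to genes came to 22582345 to 29812705 per primary library, 26349346 to 36730443 per SIRMu-1 library and 27351014 to 38125630 per rMC-1 library. The 10 most abundant genes took 12.8% to 22.9% of the counts in primary libraries, led by Col1a1 or Fn1, and 13.7% to 18.2% in SIRMu-1, led by Thbs1, Fn1 or Col1a1. In rMC-1 they took 4.01% to 4.31%, led by Actb, and the TMM factors there were 1.255 to 1.284 against 0.839 to 1.006 in the other 2 groups.

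The first comparison asked which line lies closer to the primary cultures over all tested genes. SIRMu-1 libraries had a Pearson correlation across genes of 0.874 ± 0.01 (SD, n = 5) with the mean of the primary libraries, and rMC-1 libraries of 0.717 ± 0.0059 (SD, n = 3). Each primary library had 0.963 ± 0.0097 (SD, n = 4) with the mean of the other 3. The lines differed by 0.157 (two-sided exact permutation test, p = 0.0179, the smallest that the 56 splits allow), and the 5 SIRMu-1 values of 0.859 to 0.885 all lay above the 3 rMC-1 values of 0.713 to 0.723. Genes are not independent replicates, so the test rests on the 8 libraries of the lines. Passage, serum, drugs, age of the donors and route of immortalization also differed between the lines. Serum was the same in SIRMu-1 and primary cultures and lower in rMC-1. The part of these factors in the closeness cannot be told apart from that of the line. With libraries of the same file-name code summed the difference was 0.1640, and the 2 SIRMu-1 and 2 rMC-1 samples left allow no p under 0.3333 (two-sided exact permutation test). The root mean square log2 fold change from primary cultures, less its error, was 2.08 for SIRMu-1 and 3.05 for rMC-1. No retinal tissue was measured, so closeness to the primary cultures is not closeness to Müller glia of the retina. In primary libraries the median was 3.49 to 5.22 log2 CPM for Müller glia markers and 8.79 to 10.07 for fibroblast and matrix genes. Over all of them the Müller channel genes Aqp4 and Kcnj10 had 2 and 13 counts.

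**Figure D1:**
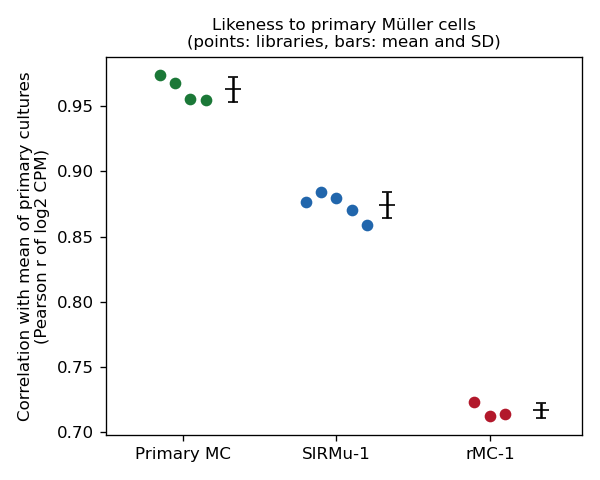
Pearson correlation across genes of log2 CPM of each library with the mean of the primary libraries (y axis, no unit) for primary, SIRMu-1 and rMC-1 cultures; points are libraries, bars mean and SD, and each primary library is set against the other 3. SIRMu-1 lay at 0.859 to 0.885, rMC-1 at 0.713 to 0.723 and primary libraries at 0.955 to 0.974.

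SIRMu-1 was then compared with the primary cultures. Genes of cell division were far higher in the line. Mki67, a marker of cycling cells, stood at 201 ± 104 CPM (SD, n = 5) against 11.4 ± 2.83 (SD, n = 4), a log2 fold change of 4.14 ± 0.51 (edgeR adjusted p = 8.90e-05). All 27 mitotic and replication genes rose, with a median log2 fold change of 3.17, and 27 rose also when adjusted over the list alone (camera adjusted p = 2.81e-13, and 0.325 with an estimated correlation). SIRMu-1 replicate 2 stood apart, with a list median of 4.10 log2 CPM against 5.55 to 6.19 in the other SIRMu-1 libraries. All 27 still rose with any 1 library left out. Cenpf, a kinetochore protein, rose by 4.30 ± 0.50. Of the 23 E2F targets of the G1/S step, 21 rose and 2 did not pass (22 rose adjusted over the list alone), with a median of 1.98 (camera adjusted p = 3.73e-10; adjusted p = 0.325 with an estimated correlation). Among them Tk1, thymidine kinase, rose by 3.93 ± 0.41 and the transcription factor gene Mybl2 by 3.90 ± 0.51. Genes of cytosolic ribosomal proteins were also higher, 73 of 75 with 1 lower and a median of 1.32 (74 and 1 adjusted over the list alone; camera adjusted p = 1.38e-28; adjusted p = 0.283 with an estimated correlation). Their counts are uncertain because of pseudogenes.

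**Figure D2:**
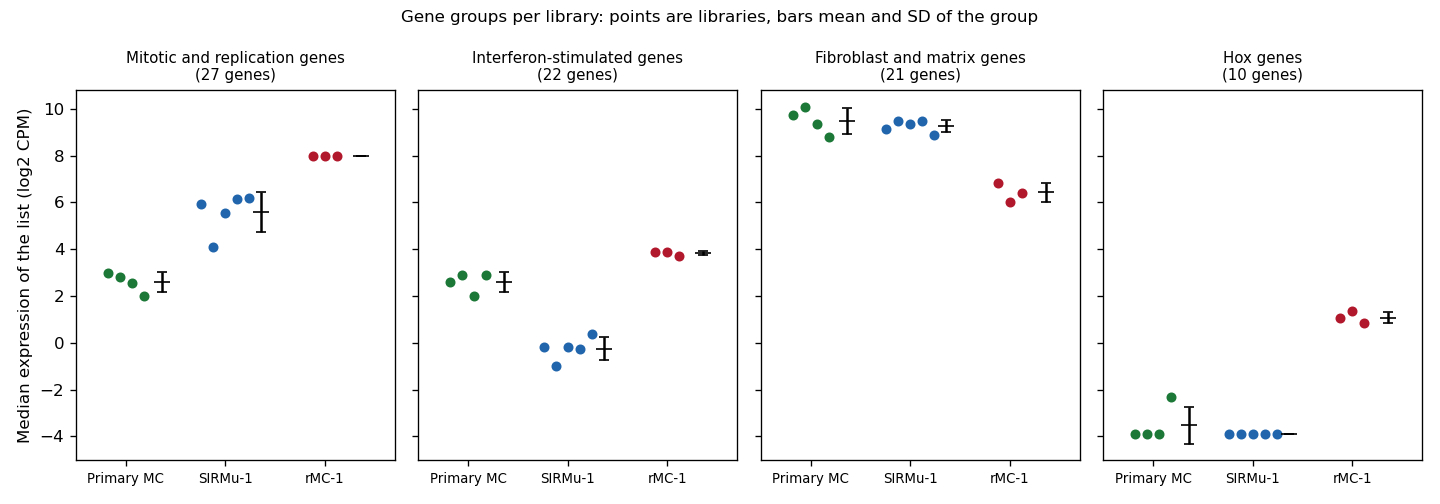
Median log2 CPM per library (y axis) of 4 gene lists in primary, SIRMu-1 and rMC-1 cultures: 27 mitotic and replication, 22 interferon-stimulated, 21 fibroblast and matrix, and 10 Hox genes; points are libraries, bars mean and SD. Mitotic medians were 2.01 to 2.99, 4.10 to 6.19 and at least 7.98, interferon medians up to 2.90, up to 0.38 and 3.72 to 3.88; Hox medians of all SIRMu-1 and 3 primary libraries lay at -3.91, the value of a count of 0.

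Genes that mark Müller glia were in part lower in SIRMu-1. Of the 25 tested, 15 fell, none rose and 10 did not pass, with a median of -1.33 (15 adjusted over the list alone; camera adjusted p = 0.0092; adjusted p = 0.499 with an estimated correlation). Glul, the glutamine synthetase of these cells, fell from 143 ± 68.6 CPM (SD, n = 4) to 56.8 ± 18.2 (SD, n = 5), a log2 change of -1.33 ± 0.31 (edgeR adjusted p = 0.00444). The intermediate filament gene Vim fell from 6207 ± 693 to 3540 ± 523 CPM (-0.81 ± 0.14, adjusted p = 0.000712). Cd44 changed by -1.56 ± 0.33 and Apoe by -6.43 ± 0.34, from 224 ± 89.2 to 2.61 ± 0.626 CPM (edgeR adjusted p = 3.31e-07), the largest fall by the rule for abundant genes. Less abundant genes of the list were lost outright, since Car2 and Sox2 had no counts in SIRMu-1. Car2 was at least 351-fold lower (725 counts in primary cultures) and Sox2 at least 112-fold lower (231 counts). Their fitted log2 changes of -10.84 and -9.22 were -10.02 and -7.24 without primary replicate 4, and both stayed called. Gfap, a glial filament gene raised in stressed Müller cells, changed by -2.80 ± 0.64, or -1.39 without primary replicate 4, and S100b by -4.52 ± 0.81, or -3.02 without that library. Sox9, a glial transcription factor, stood at 71.6 ± 31.3 against 52.2 ± 21.5 CPM (0.46 ± 0.40, edgeR adjusted p = 0.374). With libraries that share a code in their file names summed, the calls of Glul (edgeR adjusted p = 0.0964), Cd44 (0.0870) and Gfap (0.0756) were lost. The glutamate transporter gene Slc1a3 had -0.57 ± 0.30 (edgeR adjusted p = 0.135, and -0.82 with 0.0104 without primary replicate 3) and Rlbp1, which encodes a retinal-binding protein, 1.25 ± 0.65 (0.136). The water channel gene Aqp4 had 2 counts over all primary libraries and none in SIRMu-1, and the potassium channel gene Kcnj10 had 13 and none, so neither was tested. Potassium and water channel genes as a list had 7 of 10 lower and a median of -1.52 (7 adjusted over the list alone; camera adjusted p = 0.0421; adjusted p = 0.251 with an estimated correlation). That call was lost without primary replicate 3 (0.108), rMC-1 replicate 1 (0.0602), 2 (0.0542) or 3 (0.0546), or SIRMu-1 replicate 5 (0.0665), or with a filter at 1 CPM (0.135) or the codes summed (0.0605) or the replicate number as a block (0.0503), and the count was 4 without SIRMu-1 replicate 1.

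Genes of inflammation and of the interferon response were lower in SIRMu-1 as well. Of 22 interferon-stimulated genes, 17 fell and 5 did not pass, with a median of -1.71 (18 adjusted over the list alone; camera adjusted p = 2.60e-06; adjusted p = 0.251 with an estimated correlation). Psmb8, a subunit of the immunoproteasome, fell from 4.57 to 0.0726 CPM (-5.92 ± 0.46), and Rsad2, an antiviral gene, was at least 16.5-fold lower. Of 17 inflammatory genes, 14 fell and 3 did not pass, with a median of -3.44 (15 adjusted over the list alone; camera adjusted p = 2.84e-06; adjusted p = 0.251 with an estimated correlation). Markers of microglia and macrophages, the immune cells of the retina, had a median of -1.40 in the same comparison (camera adjusted p = 0.273). Lysosome genes fell in 15 of 21 cases with a median of -0.98 (15 adjusted over the list alone; camera adjusted p = 2.76e-06; adjusted p = 0.251 with an estimated correlation), among them the protease genes Ctsl (-2.15 ± 0.16) and Ctsd (-1.75 ± 0.18).

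Metabolic lists were compared as well. Of 19 glycolysis genes, 10 fell and none rose, with a median of -0.48 (12 adjusted over the list alone; camera adjusted p = 0.00588; adjusted p = 0.414 with an estimated correlation). The phosphofructokinase gene Pfkp changed by -1.48 ± 0.26. Of 23 cholesterol synthesis genes, 8 rose and none fell, with a median of 0.73 (7 adjusted over the list alone; camera adjusted p = 0.0245; adjusted p = 0.750 with an estimated correlation). Idi1 rose by 1.53 ± 0.29 and Fdps by 1.46 ± 0.29, and without SIRMu-1 replicate 5 the list's camera adjusted p was 0.0869, and with the replicate number as a block 0.0971. Fibroblast and matrix genes, abundant in both cultures, had 2 higher and 6 lower of 21 and a median of -0.28 (the same counts adjusted over the list alone; camera adjusted p = 0.374). Fbn1, which encodes fibrillin, rose from 2370 to 4749 CPM (1.00 ± 0.27), a call lost with the codes summed (edgeR adjusted p = 0.0923). Larger were the falls of Thy1 (log2 change -14.09, or -14.70 without SIRMu-1 replicate 5) and Dcn. Dcn changed by -7.23, or -5.82 without primary replicate 2 and -10.14 without SIRMu-1 replicate 5.

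Regulators of the cell cycle arrest that limits primary cultures were measured next. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, fell from 1177 ± 527 CPM (SD, n = 4) to 419 ± 166 (SD, n = 5), a log2 change of -1.49 ± 0.32 (edgeR adjusted p = 0.00269). Cdkn2b, encoding the related inhibitor p15, changed by -1.66 ± 0.42 (0.00725). Cdkn2a, whose products include p16, stood at 27.3 ± 2.88 CPM in SIRMu-1 and 68.4 ± 63.0 in primary cultures (-1.32 ± 0.41), with primary replicate 4 at 163 CPM and the others at 32.1 to 43.5, and the change was -0.44 without that library and not past the threshold with the codes summed (edgeR adjusted p = 0.160). Neither the telomerase gene Tert (-0.33 ± 0.45, edgeR adjusted p = 0.576) nor Myc (0.02 ± 0.25, 0.962) passed. Lmnb1, a nuclear lamina gene that is lost in senescent cells, rose by 3.33 ± 0.39 and the inhibitor gene Cdkn2c by 3.42 ± 0.34.

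In all, edgeR called 5220 of 11321 genes (46.1%) between SIRMu-1 and primary cultures, 2454 higher and 2766 lower in the line. With a 2-fold minimum there were 773 higher and 1759 lower. With libraries of the same code summed, 3072 genes were called. Among called genes with a mean log2 CPM over all libraries of at least 3 and no overlap between the groups, the largest rises apart from Cenpf were by 6.21 ± 0.86 for Lrp2, an endocytic receptor gene (6.87 without primary replicate 4), 5.43 ± 1.20 for the elastin gene Eln (6.37 without primary replicate 3), 4.82 ± 0.46 for Olr59 and 4.19 ± 0.59 for Cenpt. Apart from Apoe, the genes with the largest falls by this rule fell by 5.88 ± 0.47 for Grem1, a BMP antagonist that went from 12890 to 219 CPM, 5.18 ± 0.64 for Sirpa (6.38 without SIRMu-1 replicate 5), 4.45 ± 0.84 for Uchl1 and 4.44 ± 0.50 for the secreted superoxide dismutase gene Sod3.

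The comparison of rMC-1 with primary cultures gave the background against which the new line can be set. Division genes were higher still. Mki67 stood at 592 ± 26.0 CPM (SD, n = 3), a log2 fold change of 5.70 ± 0.56 (edgeR adjusted p = 4.02e-06), and the topoisomerase gene Top2a went from 12.3 to 1000 CPM (6.35 ± 0.57). All 27 mitotic and replication genes rose, with a median of 5.17 (27 adjusted over the list alone; camera adjusted p = 5.02e-12; adjusted p = 0.335 with an estimated correlation), and so did all 23 E2F targets, with a median of 4.13 (23 adjusted over the list alone; camera adjusted p = 5.61e-11; adjusted p = 0.335 with an estimated correlation). Among genes chosen by the rule for abundant genes without overlap, the largest rises were in the replication genes Cdc45 (6.89 ± 0.53) and Mcm5 (6.73 ± 0.60), in Mybl2 (6.61 ± 0.59) and in the mitotic gene Cdca3 (6.51 ± 0.56). Ribosomal protein genes rose in 70 of 75 cases with 1 lower and a median of 1.26 (70 and 1 adjusted over the list alone; camera adjusted p = 6.12e-14; adjusted p = 0.392 with an estimated correlation).

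Fibroblast and matrix genes were lower in rMC-1 than in primary cultures. Of the 21 tested, 19 fell and 1 rose, with a median of -4.14 (19 and 1 adjusted over the list alone; camera adjusted p = 2.37e-05; adjusted p = 0.306 with an estimated correlation). Postn, which encodes periostin, went from 9469 to 3.87 CPM (-11.26 ± 1.07, or -12.04 without rMC-1 replicate 1). Pericyte and smooth muscle markers fell in 11 of 13 cases, with a median of -3.27 (11 adjusted over the list alone; camera adjusted p = 0.00632; adjusted p = 0.306 with an estimated correlation). Among the largest falls by the same rule, Col15a1, a collagen gene, was at least 11310-fold lower. The ratio of primary to rMC-1 was 12455 for Stmn2 (95% counting interval 3447 to 102852), 13440 for Prl8a9 (2412 to 530888), 9266 for Ntm (3170 to 44936) and 11669 for Galnt13 (2094 to 460960). The size of their fitted log2 changes moved when single libraries were left out, while the calls held. Col15a1 went from -15.99 to -14.45 without primary replicate 1, which also gave -12.39 for Stmn2 and -12.43 for Prl8a9, from -13.26 and -13.13. Without rMC-1 replicate 2 they were -12.57 for Stmn2, -14.59 for Prl8a9, -12.23 for Ntm (from -12.95) and -12.31 for Galnt13 (from -12.92), and without replicate 3 they were -15.52 for Stmn2, -15.70 for Ntm and -14.45 for Galnt13.

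Müller glia markers went both ways in rMC-1, with 5 higher, 16 lower and 4 not past of 25 and a median of -1.38 (6 higher and 16 lower adjusted over the list alone; camera adjusted p = 0.154). Sox9 went from 52.2 ± 21.5 CPM (SD, n = 4) to 0.0358 ± 0.0400 (SD, n = 3), a log2 change of -10.45 ± 0.85 (edgeR adjusted p = 9.74e-07), or -9.72 without rMC-1 replicate 2 and -11.58 without replicate 3. Vim changed by -2.18 ± 0.17, S100b by -4.27 ± 0.98 (-2.77 without primary replicate 4) and Glul by -1.38 ± 0.36 (edgeR adjusted p = 0.00500). Cd44 changed by -1.12 ± 0.38 (adjusted p = 0.0201), a call lost without primary replicate 2 (-0.95) or rMC-1 replicate 1 (-1.02), 2 (-1.08) or 3 (-1.03). Rlbp1 rose by 3.76 ± 0.65, though only from 0.0654 to 0.910 CPM, and the eye-field gene Lhx2 by 3.59 ± 0.57. Gfap had -1.05 ± 0.71 (edgeR adjusted p = 0.201) and Slc1a3 0.69 ± 0.34 (0.0827, and 0.98 with 0.0160 without primary replicate 4). Kcnj10 had 9 counts in all rMC-1 libraries and Aqp4 none. Scaling by library totals gave -0.95 for Glul (0.0549) and -0.67 for Cd44 (0.148), which ended both calls, and 1.13 for Slc1a3 (0.0139). With the codes summed the calls of Glul (0.0522) and Cd44 (0.160) were lost as well. Channel genes had 8 of 10 lower and a median of -2.44 (9 adjusted over the list alone; camera adjusted p = 0.0456; adjusted p = 0.306 with an estimated correlation), a call lost without rMC-1 replicate 1 (0.0541, with 5 lower) or 3 (0.0540) or SIRMu-1 replicate 5 (0.0517), and with a filter at 1 CPM (0.0710).

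Interferon-stimulated genes were higher in rMC-1 than in primary cultures, 13 of 22 with 2 lower and a median of 1.10 (13 and 2 adjusted over the list alone; camera adjusted p = 0.00446; adjusted p = 0.335 with an estimated correlation). Bst2, which encodes the antiviral protein tetherin, rose from 0.346 to 62.7 CPM (7.50 ± 0.45) and Oasl by 5.26 ± 0.37, while the transcription factor gene Irf7 fell (-1.73 ± 0.39). Hox genes, which set position along the body axis, rose in 8 of 10 cases with 1 lower and a median of 5.24, or 4.99 with genes without counts at their bound (8 and 1 adjusted over the list alone; camera adjusted p = 7.15e-05; adjusted p = 0.306 with an estimated correlation). Hoxb9 was at least 802-fold higher, at 24.7 CPM. Of 25 Hox genes counted, 15 were not tested. The median of the 10 tested lay at the value of no counts in all SIRMu-1 and most primary libraries. Genes among the 10 could therefore pass the expression filter through rMC-1 alone, and the number higher there is in part set by that filter. In SIRMu-1 the Hox list had a median of -3.09 against primary cultures, or -2.04 at the bound (camera adjusted p = 0.226).

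Lysosome genes fell in rMC-1 in 17 of 21 cases with 2 higher and a median of -1.89 (17 and 2 adjusted over the list alone; camera adjusted p = 7.14e-05; adjusted p = 0.306 with an estimated correlation), with Neu1, a sialidase gene, at -3.69 ± 0.32. Cholesterol synthesis genes rose in 16 of 23 cases with none lower and a median of 1.39 (16 adjusted over the list alone; camera adjusted p = 0.000213; adjusted p = 0.558 with an estimated correlation), led by Dhcr7 (3.03 ± 0.40) and Stard4 (3.02 ± 0.49). Inflammatory genes had 12 of 17 lower, 2 higher and a median of -4.58 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0663, but 0.0454 without primary replicate 2, 0.0494 without rMC-1 replicate 1 and 0.0299 with the codes summed). Glycolysis genes had 6 higher and 5 lower of 19 (6 and 5 adjusted over the list alone, with 3 lower without rMC-1 replicate 1; camera adjusted p = 0.883), with a median of -0.07 and a camera direction upward. Slc16a1, a lactate transporter gene, rose by 1.92 ± 0.29 and Ldhb fell by 2.03 ± 0.19.

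Among growth regulators, Cdkn1a fell in rMC-1 to 33.6 ± 4.03 CPM (-5.13 ± 0.45, edgeR adjusted p = 1.70e-06) and Cdkn2b changed by -1.69 ± 0.50 (0.00976). Myc rose to 101 CPM (2.34 ± 0.28), while Tert changed by -2.67 ± 0.58 and the cyclin gene Ccnd2 by -11.33 ± 0.31. Cdkn2a had 0.36 ± 0.46 (edgeR adjusted p = 0.497), or 1.24 (1.86e-05) without primary replicate 4.

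EdgeR called 8017 of 11321 genes (70.8%) between rMC-1 and primary cultures, 3614 higher and 4403 lower, and with a 2-fold minimum 2041 and 3154. Scaling by library totals moved the median log2 fold change of all genes from -0.149 to 0.323 and the share of higher calls from 45.1% to 61.9%, so directions here hold relative to the TMM scale. Under it the list medians of senescence regulators (-0.02 to 0.46), glycolysis (-0.07 to 0.39), HIF target (-0.15 to 0.33) and stress genes (-0.20 to 0.27) changed sign, and those of the lists called by camera did not. Both lines were set against the same primary libraries, which makes their changes overlap by chance. In both lines 1673 genes were called higher and 1878 lower, and 567 went opposite ways, where independent lists would share 783 and 1076. The log2 fold changes of the lines had a correlation across genes of 0.520 and a covariance of 3.210. In 50 simulations of unchanged lines against these libraries the mean correlation was 0.496, the mean covariance 0.087 (highest 0.097) and no call was shared. Lines without change can give hardly any calls, so the lack of shared calls is no background for the overlap. The observed correlation lay under the highest simulated value of 0.534 and alone shows no shared change, while the observed covariance lay above the simulated ones. With the primary libraries split 2 and 2, each line against its own pair, the medians over the 6 fits were 1244 genes higher, 1492 lower and 463 opposite, beside 555 and 839 for independent lists, with a correlation of 0.463 and a covariance of 2.872.

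SIRMu-1 and rMC-1 were finally compared directly, without the primary cultures as the reference. SIRMu-1 had lower division genes and higher matrix genes. Of the mitotic and replication genes 26 of 27 were lower, with a median of -2.10 (26 adjusted over the list alone; camera adjusted p = 5.55e-07; adjusted p = 0.691 with an estimated correlation), among them Mcm7 (-3.17 ± 0.25) and Mki67 (-1.56 ± 0.45, edgeR adjusted p = 0.0102). Of the E2F targets 21 of 23 were lower, with a median of -2.24 (21 adjusted over the list alone; camera adjusted p = 4.44e-07; adjusted p = 0.691 with an estimated correlation), with Cdt1 at -3.65 ± 0.43 and Brca1 at -3.21 ± 0.32. Fibroblast and matrix genes were higher in 17 of 21 cases and lower in 1, with a median of 3.04 (17 and 1 adjusted over the list alone; camera adjusted p = 5.70e-05; adjusted p = 0.457 with an estimated correlation). Pericyte and smooth muscle markers were higher in 8 of 13 and lower in 1, with a median of 2.93 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0161; adjusted p = 0.457 with an estimated correlation), with Myocd, a smooth muscle coactivator gene, at 10.57 ± 1.04 and Cspg4 at 10.21 ± 1.36.

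Interferon-stimulated genes differed between the lines, 19 of 22 being lower and 1 higher in SIRMu-1, with a median of -4.51 (19 and 1 adjusted over the list alone; camera adjusted p = 4.44e-07; adjusted p = 0.200 with an estimated correlation). Oasl was at least 226-fold lower, and Bst2 changed by -10.63 ± 0.51, or -11.46 without SIRMu-1 replicate 4. Hox genes were lower in 9 of 10 cases, with a median of -8.51, or -6.18 at the bound (9 adjusted over the list alone; camera adjusted p = 1.40e-06; adjusted p = 0.338 with an estimated correlation), and Hoxb9 was at least 1165-fold lower. As above, the other Hox genes were not tested, and the count of 9 is in part set by the expression filter. Lysosome genes were higher in 12 of 21 and lower in 3, with a median of 0.55, or 0.10 with library totals (12 and 3 adjusted over the list alone; camera adjusted p = 0.0217; adjusted p = 0.691 with an estimated correlation). Cholesterol synthesis genes were lower in 13 of 23 and higher in none, with a median of -0.95 (13 adjusted over the list alone; camera adjusted p = 0.00503; adjusted p = 0.691 with an estimated correlation).

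Müller glia markers divided between the lines, with 8 higher and 9 lower in SIRMu-1 of 25 and a median of -0.25 (8 and 9 adjusted over the list alone; camera adjusted p = 0.798). Sox9 was higher (10.91 ± 0.85, edgeR adjusted p = 1.08e-06, or 10.15 without rMC-1 replicate 2 and 12.02 without replicate 3), as was Vim (1.37 ± 0.16). Sox2, another glial and progenitor transcription factor gene, was at least 684-fold lower. Slc1a3 (-1.27 ± 0.32) and Rlbp1 (-2.51 ± 0.53) were lower, and so was Gfap (-1.75 ± 0.66, edgeR adjusted p = 0.0359), though not without rMC-1 replicate 1 (0.0835) or 2 (0.0510) or SIRMu-1 replicate 2 (0.0717), 3 (0.0508) or 4 (0.0648). With the codes summed Gfap (0.201), Slc1a3 (0.0984) and Cdkn2a (0.0984) did not pass. Glul (0.05 ± 0.34, 0.911), S100b (-0.25 ± 0.86, 0.818) and Cd44 (-0.44 ± 0.35, 0.291) did not pass, and Cd44 did with library totals (-0.89, 0.0491). Cdkn1a was higher in SIRMu-1 (3.64 ± 0.41), as was Tert (2.34 ± 0.56), while Myc (-2.33 ± 0.26) and Cdkn2a (-1.69 ± 0.44) were lower and Cdkn2b did not differ past its error (0.03 ± 0.45, edgeR adjusted p = 0.967).

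EdgeR called 7157 genes (63.2%) between the lines, 3702 higher and 3455 lower in SIRMu-1, and with a 2-fold minimum 2270 and 1830. Which direction held the majority was not stable. The share of higher calls, 51.7%, was 45.4% to 46.5% without any 1 rMC-1 library, and 47.1% without SIRMu-1 replicate 5, with only the drug-free SIRMu-1 libraries or with libraries of the same code summed. With library totals it was 30.8%, and the median of all genes -0.403 in place of 0.030. List medians that then changed sign were those of photoreceptor (0.32 to -0.13), senescence (0.21 to -0.24), retinoid (0.26 to -0.19), stress (0.09 to -0.37) and ribosomal protein genes (0.10 to -0.34). Ribosomal protein genes had 12 higher and 5 lower of 75 on the TMM scale, with 4 to 21 higher and 5 to 12 lower when 1 library was left out, the fewest higher without rMC-1 replicate 1 (4 and 4 adjusted over the list alone; camera adjusted p = 0.690). The largest differences by the rule for abundant genes without overlap were in Cdhr1, a cadherin gene of photoreceptors (at least 23199-fold higher), Epb41l3 (at least 3583-fold), Olr59 (ratio 27603, 95% counting interval 4954 to 1090313; fitted 14.17, or 15.70 without rMC-1 replicate 1 and 13.54 without replicate 2), the fibrillin gene Fbn2 (13.36 ± 1.08) and Itgbl1 (13.83 ± 1.26, 14.76 without rMC-1 replicate 2). Fam111a changed by -6.81 ± 0.60, Sirpa by -7.41 ± 0.71, Celsr2 by -7.13 ± 0.74 and Cdh3 by -6.51 ± 0.74, the last 3 being -8.68, -7.73 and -7.56 without SIRMu-1 replicate 5, and Tnn by -6.03 ± 1.23 (-6.70 without SIRMu-1 replicate 4, and an adjusted p of 0.0688 with the codes summed).

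Gentamicin and amphotericin B were tested within SIRMu-1, where 2 cultures had them and 3 did not. No gene was called by edgeR's quasi-likelihood test, with 433 genes at an unadjusted p under 0.05, and limma on the authors' table called none either, nor did edgeR with the file-name code as a term (333). DESeq2 called 3 genes, named here after their values were seen. Gpnmb, a glycoprotein gene of lysosomes and melanosomes, stood at 37.7 to 78.8 CPM with the drugs and 9.63 to 20.3 without (1.87, DESeq2 adjusted p = 0.00741), Snai1, a transcription factor gene, at 146 to 344 and 29.6 to 63.4 (2.25, 0.0370), and Snap47 at 8.73 to 11.1 and 14.8 to 19.5 (-0.77, 0.0372). Without SIRMu-1 replicate 3 edgeR called Ptn (5.13) and Gdpd2 (5.05), also named after the fact, with 1 culture left on the drugs, that of passage 20. In simulated data this comparison called 68.2% of genes changed 4-fold and 1.5% of those changed 1.5-fold, so small effects were not detectable. Passage number was fitted across the SIRMu-1 cultures with the drug term, and edgeR called no gene of 10755, with 447 at an unadjusted p under 0.05. Without the drug term it called none and 1384 were under 0.05, with the file-name code as a term it called none and 832 were, and no other tool was run on it. The fit had 2 residual degrees of freedom, and 3 of the 5 cultures shared passage 11.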

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

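All tests of explanations in this part were chosen after the results were seen. Dixon's test for a library far from the others of its group was run on 36 groups over 18 measures, and it picked out 4, where chance gives about 1 in 20. These were primary and SIRMu-1 groups only, since rMC-1 had too few libraries for the test. Gfap stood at a log2 CPM of 4.27 in primary replicate 4, with 1.11 to 1.62 in the others. S100b stood at -3.21 in SIRMu-1 replicate 3, with -1.34 to -0.81 in the others, a low value near the -3.91 of a gene without counts. Cd44 stood at 7.59 in primary replicate 3, with 9.26 to 9.51 in the others. Mki67 stood at 5.28 in SIRMu-1 replicate 2, with 7.44 to 8.31 in the others. The change of interferon-stimulated genes from primary cultures differed between the lines, with a median of -4.51 on the log2 scale in the direct test of SIRMu-1 against rMC-1.

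Interferon-stimulated genes lay below the primary level in SIRMu-1 and above it in rMC-1. A wrong scaling factor moves all genes of a library alike. Scaling alone is therefore argued against by the distance of the list median from the median of all genes. It was -1.70 in SIRMu-1 (95% bootstrap interval over the 22 genes -4.04 to -1.07) and 1.25 in rMC-1 (0.36 to 2.48). These intervals take genes as units and leave out the spread between libraries. With an estimated correlation, camera gave the list an adjusted p of 0.251 in SIRMu-1 and 0.335 in rMC-1. The drugs are argued against for SIRMu-1, where 11 of the 17 genes were still lower when the SIRMu-1 cultures with drugs alone were used, while in rMC-1, which had none, drugs and cell type cannot be told apart (within SIRMu-1 the list changed by 0.11 with the drugs). RNA from microglia or macrophages in the primary cultures stays open as a possible source of the higher level there: the 16 markers had a median of 0.482 CPM in primary cultures, 18.6% of the 2.59 CPM of the 17 genes that fell, above the bound of 10% set for excluding it. Of these markers 6 were abundant enough to test, led by Tmem119 at 308 CPM, which SIRMu-1 also held at 184 CPM, then Csf1r at 3.11 CPM. Microglia in the primary cultures would not enter the direct test of the lines. Age of the donors, serum, passage, the level of Y-linked genes and the route of immortalization differ between the lines as well, and their part in this difference was not tested.

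In SIRMu-1 replicate 2 all 27 mitotic and replication genes were lower than in each other SIRMu-1 library, by a median of 2.08 on the log2 scale (4.10 against 5.55 to 6.19 in replicates 1, 3 and 5). Primary cells mixed into it are argued against, because 14 genes abundant in primary cultures alone were raised there by -0.001143% of their primary level, where a mixture would need 76.3%. Passage and drugs are argued against by replicate 4, which shared both with replicate 2 and had 6.13. A larger share of counts in the 10 most abundant genes would change all others by -0.056 on the log2 scale, far less than the fall. No biological explanation was tested, and the state of the culture when it was collected stays open.

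Other groupings of the same libraries were counted for each comparison. For the genes called, the real grouping was the 1 of 100 drawn for SIRMu-1 against primary cultures with as many genes (5220, highest other 3645). It was the 1 of 35 for rMC-1 against primary cultures (8017, highest other 3404) and the 1 of 56 for the direct comparison (7157, highest other 0). This argues against chance only if each library is taken as independent. The groupings with 3645 and 3404 genes had 4 and 3 libraries of each group exchanged, close to the real groups with their names swapped, and 92 of 99, 30 of 34 and 55 of 55 other groupings gave no gene. Groupings that mix the kinds of culture widen the fitted spread, so few calls in them follow from the design. They are no background of unchanged groups. If libraries that share a file-name code count as 1 sample, the groupings are too few for a share under 0.05. For the number of lists called, chance cannot be excluded, and these groupings cannot decide it. At least the 10 lists of the first comparison came in 18 of 100 groupings (highest other 13). The second had its 10 in 15 of 35 (14) and the direct one its 8 in 10 of 56 (10). The other groupings with as many lists had 1 or 3 libraries of each group exchanged. They therefore kept part of the real difference, as it stands or with the names swapped, and are no background free of it.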

How the results depend on the processing

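Leaving out libraries in the passage fit and the list tests, and the use of file-name codes, were chosen after seeing the data. No called value of a named gene and no list called by camera changed direction under the alternatives run; the other called genes were not followed 1 by 1. Library totals turned the majority of calls in both comparisons of rMC-1, and 9 list medians not called by camera. The majority between the lines also turned without any 1 rMC-1 library, without SIRMu-1 replicate 5, with only the drug-free SIRMu-1 libraries and with codes summed, and that of SIRMu-1 against primary cultures with limma (50.6% higher). Against a 1.5-fold change, glmTreat called 2330 genes between SIRMu-1 and primary cultures and 4390 between the lines, since it asks for more than a difference from 0. With only the 2 SIRMu-1 cultures on drugs, edgeR's test against 0 called 3415 between SIRMu-1 and primary cultures, with fewer samples. With libraries of the same file-name code summed, again fewer samples, it called 3072, 7357 and 5745 genes in the 3 comparisons and camera 9, 12 and 8 lists; the correlation difference was 0.1640 and the size for rMC-1 3.121; 42 of the named gene values lost their call. DESeq2 called 3 genes for the drugs; the cause was not tested. With a filter at 1 CPM in 3 libraries, which leaves fewer genes, the size of the expression difference was 1.893 for SIRMu-1 and 2.944 for rMC-1, and it ranged over 1.891 to 2.194 and 2.968 to 3.169 with 1 library left out. Camera called 10, 10 and 8 lists, and 0, 0 and 0 with an estimated correlation; fry, which tests another question, called 16, 23 and 23. With 1 library left out the calls ranged over 4572 to 5339 (SIRMu-1 against primary), 7423 to 8201 (rMC-1 against primary) and 6249 to 7287 (direct), 0 to 2 for the drugs and 0 for passage. DESeq2 called 5889, 8604 and 7522 genes, and limma on the authors' log2 CPM called 4660, 7281 and 6736. Sets of 3 SIRMu-1 libraries, as many as rMC-1 has, gave a median of 4346.5 calls (3731 to 5008). Over all alternatives, 6599 values of named genes were on the same side of the threshold, 240 lost and 11 gained a call, and of list results 1367 were the same, 43 lost and 45 gained one. DESeq2 gave no adjusted p for 7 named gene values. Depth limits genes such as Aqp4 and Kcnj10, whose few counts were not tested.

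With the replicate number as a replicate block, 4973, 8019 and 7157 genes and 8, 10 and 9 lists were called. The numbers do not pair the samples: deviations of the same number in 2 groups had correlations of -0.063 to 0.098 (median 0.025, 10 pairs), and others -0.156 to 0.127.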

Other observations

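Genes of the Y chromosome, a sign of male cells, divided the cultures. Eif2s3y stood at 124 to 217 CPM in the 5 SIRMu-1 libraries and had no count in the 3 rMC-1 libraries, at least 6442-fold lower than in SIRMu-1. In primary libraries 1 to 3 it was at 0.711 to 1.46 CPM and in replicate 4 at 18.7, so SIRMu-1 was higher by 4.87 ± 0.98 (edgeR adjusted p = 0.00295), or 7.18 without primary replicate 4, and not past the threshold with libraries of the same file-name code summed (edgeR adjusted p = 0.0604). The gene listed as Ddx3 went the same way, at 150 to 244 CPM in SIRMu-1, 1.14 to 2.10 in primary replicates 1 to 3, 21.3 in replicate 4, and 4 counts in 1 of the 3 rMC-1 libraries. The level of these genes thus went with the kind of culture in all 3 comparisons. Any part of sex in the other differences cannot be told apart from that of the kind of culture.

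The 14 remaining gene lists were not called by camera in any comparison, and are given as median log2 fold changes for SIRMu-1 against primary, rMC-1 against primary and SIRMu-1 against rMC-1, with the lowest of the 3 camera adjusted p. Retinal pigment epithelium markers had -1.83, -2.36 and -0.12 (0.0669), and growth and neurotrophic factors -1.04, -1.61 and 0.91 (0.0663, with 0.0454 without primary replicate 2, 0.0473 without rMC-1 replicate 2 and 0.0443 with the codes summed). Igf1, a growth factor gene, was lower in SIRMu-1 than in primary cultures by a ratio of 6497 (95% counting interval 2223 to 31511), with a fitted log2 change of -12.34, or -11.56 without primary replicate 2 and -13.26 without SIRMu-1 replicate 2. Retinoid handling genes had -1.34, -2.0 and 0.26 (0.137), with Rarb, a retinoic acid receptor gene, at -5.95 ± 0.58 in SIRMu-1. Progenitor genes had -0.44, 1.36 and -2.07 (0.154). Endothelial markers had -0.13, -2.33 and 2.77 (0.154), with the TGF-beta coreceptor gene Eng at -10.81 ± 1.09 in SIRMu-1 and Tek at 4.34 ± 0.37. Inner retinal neuron markers had -1.65, -6.10 (-5.75 with genes at their bound) and -0.68 (0.154), and Nefm, a neurofilament gene, was at least 1969-fold lower in SIRMu-1 than in primary cultures. The p53 targets had -0.17, -0.70 and 0.70 (0.154), and HIF targets -0.49, -0.15 and -0.51 (0.166). Astrocyte markers had -0.51, -2.92 and 1.74 (0.210), and microglia and macrophage markers -1.40, -3.32 and 1.11 (0.248). Glutamate and glutathione genes had -0.04, 0.08 and -0.23 (0.443), with the cystine transporter gene Slc7a11 at 3.29 ± 0.41 in rMC-1 against primary cultures. Senescence regulators had -0.10, -0.02 and 0.21 (0.6246), stress and immediate early genes -0.04, -0.20 and 0.09 (0.772), and the 3 photoreceptor markers tested -0.85, -0.51 and 0.32 (0.804).

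Median, mean and camera direction differed in sign for several lists. Against primary cultures, SIRMu-1 had a negative median and mean with an upward camera direction for endothelial, senescence and glutamate lists, and a positive median (0.24) with a negative mean (-0.91) and downward direction for pericyte and smooth muscle markers (0 higher and 4 lower of 13, also adjusted over the list alone; camera adjusted p = 0.804). The rMC-1 line had a negative median with an upward direction for glycolysis, HIF target and stress genes, and a mean of -0.01 for glutamate genes. In the direct comparison inflammatory genes had a median of 0.64, a mean of -0.14 and a downward direction (camera adjusted p = 0.751), stress genes a mean of -0.06 and a downward direction, and inner retinal neuron markers a mean of 1.85 and an upward direction. In that comparison channel genes had a median of 0.77 (camera adjusted p = 0.6246), and glycolysis genes of -0.42 (0.0618, with 0.0388 without primary replicate 4, 0.0383 without rMC-1 replicate 2, 0.0492 without SIRMu-1 replicate 3 and 0.0220 with the replicate number as a block).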
